A study of Drosophila melanogaster with 19 samples.

How the data were processed

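The series combines chromatin immunoprecipitation sequencing (ChIP-seq) of Grainy head (GRH), a transcription factor of epithelia, with RNA-seq of Drosophila embryos labelled as depleted of maternal or zygotic grh. It holds 19 samples. Wild-type Oregon-R embryos were collected 2-3 h, 5-6 h, 11-12 h and 15-16 h after egg laying and precipitated with 2 antibodies, labelled GRH and 1-441GRH, with 1 library per antibody and stage. Wing discs of larval instar 3 were precipitated with the GRH antibody, in 1 library. The 5 input libraries have no peak list of their own and were not analysed here. The RNA samples are 2 maternal depletions at 2-3 h (alleles grhB37 and grhIM, from germline clones), 2 zygotic depletions at 11-12 h and 1 at 15-16 h, each of 7 embryos and each set against its control within 1 table. Per the labels' protocols, total RNA was taken with TRIzol and libraries were made with an Illumina TruSeq kit.

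Per the submitters' processing notes, Bowtie, TopHat, Cufflinks, Cuffdiff and MACS were used, and both dm3 and dm6 are named as builds, with no version and no role stated. The chromosome names of the peak lists and the loci of the RNA tables follow dm3, and coordinates are given here in dm3 as the authors' files give them, counted from 1. The authors deposited 9 peak lists, each made from 1 library per the file headers, with a score per peak whose scale is not given in the sources used here. These deposited scores are the authors' own values and serve only to rank or filter peaks within a list. The lists start at different lowest scores, 50 for the GRH antibody at 2-3 h and about 60 for the other embryo lists, so their lengths are not on 1 threshold. The authors deposited 5 gene tables with an FPKM for control and depleted embryos, a log2 fold change, a p-value and a q-value, and a call at q under 0.05 per the file headers. FPKM, fragments per transcript length and library size, was normalized by the authors within each table. The depth of the libraries is unknown, since neither the lists nor the tables hold read counts. Both maternal tables are attached to both maternal samples, and each was used once, under the allele its column names give. The grhB37 table uses other gene models than the remaining 4. Loci with no symbol, or with a symbol that a table gives to more than 1 locus, were left out, which kept 13952 of 14364 loci for grhB37 and 14429 of 14540 in the 15-16 h table.

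A gene counted as changed when the authors called it at q under 0.05 in both tables of a stage in the same direction, or in the 1 table of 15-16 h. Those tests weigh the reads of a pair of libraries and compare those libraries, not the conditions. As a test on the spread between tables, limma with a trend on the mean level was fitted to log2(FPKM + 1) of depleted minus control in the 5 tables, with 1 mean per stage, over 11091 genes at FPKM of at least 1 in either column of at least 1 table. All log2 ratios given, with or without an SD, and all limma values are on this log2(FPKM + 1) scale, which understates the change of low genes. The limma test was two-sided with Benjamini-Hochberg adjusted p, and the single ratio at 15-16 h is assumed there to vary like the others. The p-values measure only the spread between these samples. On simulated ratios with 200 genes changed by a known amount among 11091, limma called 96.2%, 96% and 87.4% of 4-fold changes at 2-3 h, 11-12 h and 15-16 h and 75.6%, 74.4% and 22.8% of 2-fold changes. The false share of calls was 5.7%, 8% and 7.65%, above the nominal 5%, and the trend term had been changed once after a first simulated run. The simulation planted each change in all 5 ratios and gave each gene the same spread at every stage. Its shares therefore do not carry over to the data. At 2-3 h en, gsb and mid had log2 ratios of 2.16, 2.09 and 2.09, yet limma called none (adjusted p = 0.325, 0.325 and 0.428).

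Peaks on the 6 main arms (2L, 2R, 3L, 3R, 4 and X) were compared by overlaps of at least 1 bp, against 1000 random placements of each peak within its own arm. The smallest p these can give is 0.001, one-sided. On simulated lists with 0%, 10% and 50% planted overlaps the count came to 12.6%, 23.3% and 56.8%, against 13.96% by chance. A gene was bound when a GRH antibody peak overlapped its locus extended by 2 kb on each side, and bound genes were compared with changed genes by Fisher's exact test, two-sided. Within 4 classes of locus length the odds ratio was pooled by the Mantel-Haenszel method, whose test is not exact. Calls of different stages were compared by the same test among genes tested in both.

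Before the data were examined, 24 gene lists were fixed: known GRH targets, chitin synthesis and cuticle assembly, cuticle proteins, cuticle tanning and wound response, septate junction, adherens junction and apical polarity, apical matrix zona pellucida proteins, epidermal and tracheal regulators, innate immunity, early zygotic patterning, maternal transcripts, neuroblast, neuron, glia, muscle, hemocyte, midgut, fat body, salivary gland, germline, ecdysone pathway, heat shock and stress, ribosomal proteins, and housekeeping. Each was tested on the limma stage means with the camera formula, a comparison of a list with the other genes, at a preset correlation of 0.01, and again with a correlation estimated from the ratios. Each list's median in a table was also placed among those of 10000 random lists of the same size matched on mean expression. A gene's place in a list follows the symbols of the tables, and loci that the authors merged carry all their symbols.

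The genes named follow a rule fixed before the data were examined. It takes grh first and then, per stage, the 10 largest mean rises and the 10 largest mean falls by the deposited log2 fold change among called genes with FPKM of at least 1 in a column of each table, infinite folds left out. It adds up to 4 members of each list discussed, called ones first and then by size, the 3 highest peaks of each GRH list and the peaks at known GRH targets. Other genes are marked where they appear. The alternatives tried were other overlap rules, stricter or equal-length peak lists, other call thresholds, pseudocounts of 0.1 and 5, no filter on FPKM, other locus extensions, locus length classes, peaks shared by both antibodies, ratios centred per table, a fit of the 2-3 h stage alone, an estimated correlation and each replicate left out in turn. Peaks scoring at least 60 in every list, and counts without genes at FPKM of at least 1 in a 2-3 h control, were added after seeing the data. The planned search for the GRH motif in peaks needs a genome sequence and was not run. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with R 4.3.3 and limma 3.58.1.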

Results

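Binding of GRH was mapped by ChIP-seq in wild-type embryos at 4 ages and in larval wing discs, and RNA was measured in embryos labelled as depleted of maternal grh at 2-3 h and of zygotic grh at 11-12 h and 15-16 h. GRH is a transcription factor of the epidermis, trachea and other epithelia, known for its part in barrier formation and wound repair. The labels give 1 library per antibody and stage for ChIP, 2 RNA tables each at 2-3 h and 11-12 h, and 1 at 15-16 h. Neither the peak comparisons nor the 15-16 h RNA comparison therefore has a replicate check. Read depth is unknown, so differences in the number of peaks or calls between libraries cannot be set against depth.

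GRH bound its own gene at every embryonic stage. Within 2 kb of the grh locus (2R:13690294-13729584) there were 3 GRH antibody peaks at 2-3 h, 5 at 5-6 h, 5 at 11-12 h and 5 at 15-16 h, and 2 in the wing disc. The last of the 15-16 h peaks, 2R:13730242-13731809, lies beyond the end of the locus. The peak at 2R:13690850-13695691, inside the locus, was among the 116 peaks scoring 3100 or more at 11-12 h. Such scores were held by 6 peaks at 2-3 h, 353 at 5-6 h and 614 at 15-16 h. A score of exactly 3100 recurs at many loci, as a ceiling would give. Order by score among the highest peaks therefore need not follow strength. Other peaks leading by score lay over ed (a cell adhesion protein) at 2L:4029360-4032777 and ds (a large cadherin) at 2L:712712-716364 at 2-3 h. At 15-16 h such a peak lay over kibra (a Hippo pathway protein) at 3R:10530513-10535719. At 2-3 h the remaining leader lay over pb, a homeotic gene. At 5-6 h the leaders were at bmm, a lipase gene, in a cluster around Mdr49, and at Mipp1, and at 11-12 h CG43759 and Prosap stood above grh. The 15-16 h peak with the highest score had no gene, with CG11726 lying 7467 bp away, and a further leader covered RnpS1 and mura. In the wing disc 10 peaks tied at the highest score, among them peaks over ex (a Hippo pathway protein) and crq, over aop (an ETS repressor), and 92 bp from Rh5.

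**Figure D1:**
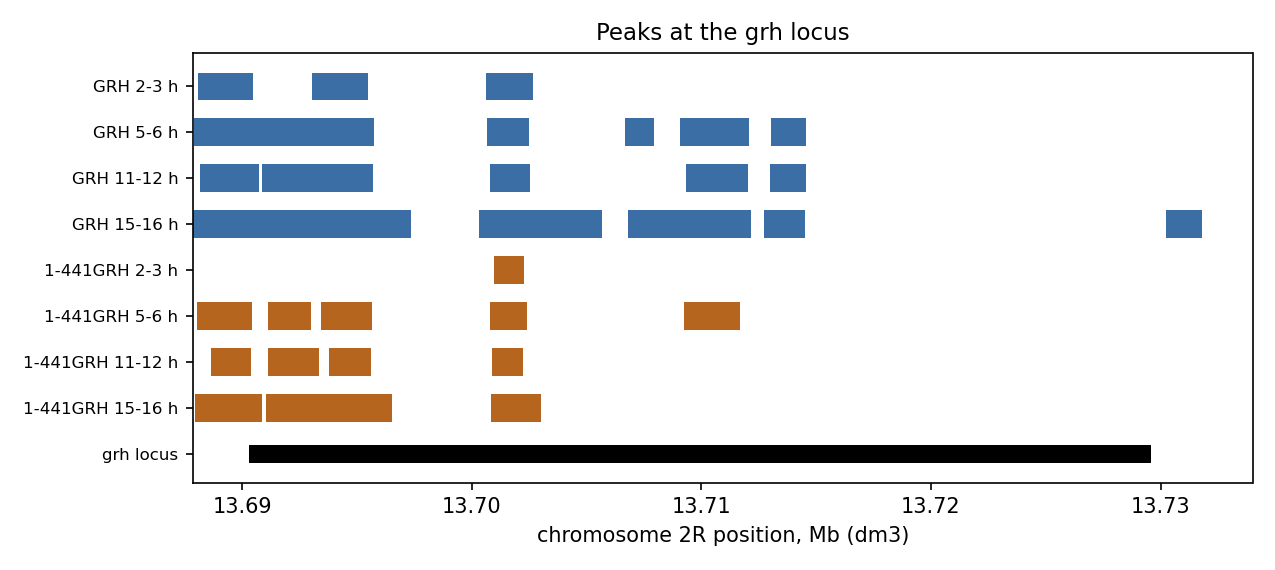
Bars mark the deposited peaks of each embryo stage along chromosome 2R (position in Mb, dm3), blue for the GRH antibody and brown for the 1-441GRH antibody, with the grh locus in black below. The GRH antibody gives 3, 5, 5 and 5 peaks within 2 kb of the locus from the youngest to the oldest stage, and the 1-441GRH antibody also marks the locus at every stage.

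Genes already known as GRH targets were bound through embryogenesis. Of 19 such genes in the tables, 13 (68.4%) had a GRH peak within 2 kb at all 4 stages, among them Ddc (dopa decarboxylase, used in cuticle tanning and wound repair), cora and vari (septate junction proteins), kkv (chitin synthase), knk, verm and serp (chitin organization), and the patterning genes dpp, Ubx and en. The others with such peaks at every stage were msn, Fas3 and mdy. The gene for tyrosine hydroxylase, ple, was bound at 3 stages, sinu, tll, Idgf4 and krz at 1, and ftz at none. Among all 14224 loci, 3900 (27.4%) were bound at all 4 stages and 8837 (62.1%) at any stage.

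Several gene lists, epithelial and other, were bound at all 4 stages more often than other genes, in a comparison added after the data were seen. The share was 16 of 18 epidermal and tracheal regulators (odds ratio 21.3, Fisher's exact test, adjusted p = 2e-06 over 24 lists), 17 of 22 chitin and cuticle assembly genes (9.04, adjusted p = 1.9e-05) and 9 of 11 glial genes (11.9, adjusted p = 0.0011). Septate junction genes reached 15 of 26 (3.62, adjusted p = 0.0041) and ecdysone pathway genes 14 of 22 (4.65, adjusted p = 0.0014). Adherens junction and apical polarity genes and apical zona pellucida proteins each had 11 of 15 (7.3, adjusted p = 0.0011). Long loci catch more peaks, and within locus length classes the adherens junction, zona pellucida and ecdysone lists no longer passed (adjusted p = 0.099, 0.083 and 0.085). Structural cuticle proteins were bound at all 4 stages in 22 of 117 cases (odds ratio 0.611, adjusted p = 0.074).

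The number of peaks differed between stages, and the regions bound early stayed bound. The GRH antibody lists hold 3004 peaks at 2-3 h, 5866 at 5-6 h, 4467 at 11-12 h and 6281 at 15-16 h, with median widths of 1825, 1715, 1679 and 2153 bp. Whether binding is stable through development was asked by overlap: of the 2968 peaks on the main arms at 2-3 h, 97.3% overlapped a peak at 5-6 h, 87.1% at 11-12 h and 96.2% at 15-16 h. All 3 later stages were reached by 2476 of them (83.4%, against 11.8% for random placements, permutation p = 0.001, the smallest that 1000 placements can give). Merging the 4 lists gave 7467 regions, of which 2251 (30.1%) were bound at all 4 stages and 2662 (35.6%) at 1 stage. Regions seen at 1 stage numbered 6 at 2-3 h, 730 at 5-6 h, 195 at 11-12 h and 1731 at 15-16 h. Regions of all 4 stages were also in a 1-441GRH list in 82.1% of cases and in the wing disc list in 41.0%, against 3.72% and 3.49% for regions of 1 stage. Their median widths were 3328 and 1533 bp, and wider regions meet more peaks by chance, which was not computed for these shares. Overlap of 1 bp is a loose rule. With midpoints within 100 bp the share at all 3 later stages was 9.33%, and with a reciprocal overlap of 50% it was 53.9%. With each list cut to its 429 highest scores it was 29.6%. Each was above its chance value. At 15-16 h 614 peaks scored 3100 or more, so that cut fell among tied scores and kept peaks by position. The equal-length shares were 76.5% at 5-6 h, 73.7% at 11-12 h and 44.1% at 15-16 h, so the last and the 29.6% partly reflect those ties.

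Nearly all 1-441GRH peaks overlapped GRH antibody peaks, in 1 library of each per stage. The converse did not hold, since the GRH antibody lists are far longer. The shorter 1-441GRH lists (506, 1916, 1394 and 2092 peaks from the youngest to the oldest stage) overlapped GRH antibody peaks in 96.7%, 99.5%, 92.2% and 96.2% of cases, against 8.65%, 18.4%, 12.7% and 23.4% by chance (permutation p = 0.001 at each stage, the smallest possible). Midpoints within 100 bp were found for 25.6% to 40.0% of them and a reciprocal overlap of 50% for 58.7% to 75.6%. With equal-length lists the share was 48.3% to 82.8%. It was lowest at 15-16 h, where tied scores left the cut of the GRH antibody list to position.

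Wing disc peaks lay mostly where embryos were bound. Of 1401 wing disc peaks on the main arms, 1296 (92.5%) overlapped an embryo GRH peak of some stage, against 27.2% by chance (permutation p = 0.001, the smallest possible). By stage the share was 71.8% at 2-3 h, 86.7% at 5-6 h, 79.7% at 11-12 h and 88.0% at 15-16 h. Of the wing disc peaks, 962 (68.7%) overlapped a peak in each of the 4 embryo lists, and 105 (7.49%) overlapped no embryo peak. With midpoints within 100 bp the share with any embryo stage was 18.6%, with a reciprocal overlap of 50% it was 54.3%, and with equal-length lists 65.0%. The 15-16 h list that enters the equal-length share was cut by position among tied scores.

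**Figure D2:**
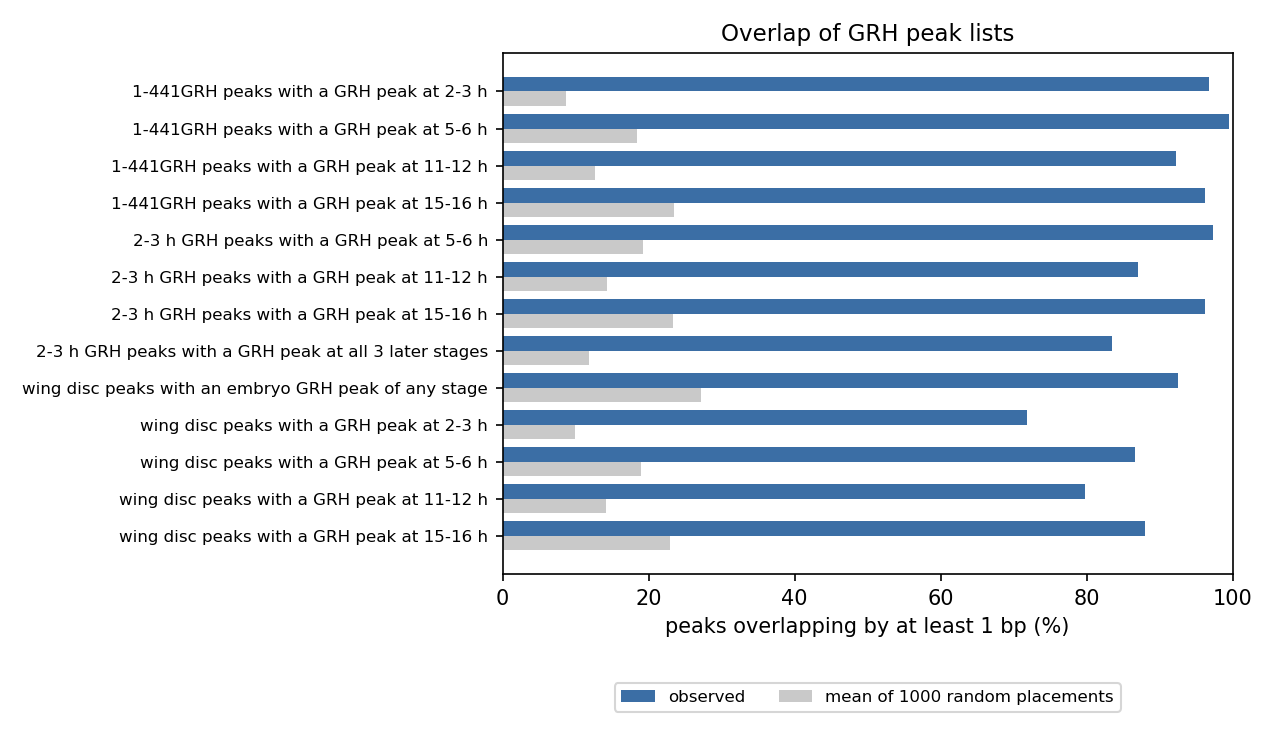
Blue bars give the percentage of peaks in the first list of each pair that overlap a peak of the other list by at least 1 bp, and grey bars the mean over 1000 random placements. Observed shares run from 71.8% (wing disc with 2-3 h embryos) to 99.5% (both antibodies at 5-6 h), and chance stays at or below 27.2%.

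The targeted gene was measured first in each RNA table. In the authors' deposited tables grh had an FPKM of 57.7 in the control and 49.0 in the depleted embryos for grhB37, 16.7 and 15.2 for grhIM, 53.3 and 52.4 in replicate 1 at 11-12 h, 54.4 and 54.2 in replicate 2, and 35.4 and 54.5 at 15-16 h. The mean log2 ratio was -0.18 ± 0.07 (SD, n = 2) at 2-3 h and -0.01 ± 0.01 (SD, n = 2) at 11-12 h, with limma adjusted p = 0.666 and 0.928, and 0.61 at 15-16 h (limma adjusted p = 0.0491). The level of grh RNA does not test alleles that act on the protein, so the tables leave the labels unchecked.

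Embryos depleted of maternal grh had more RNA of a small set of regulatory and cell surface genes at 2-3 h with both alleles. The authors' deposited tables called 8 genes higher in both and 0 lower, with 56 higher and 10 lower at unadjusted p under 0.05 in both by Cuffdiff. They were the segmentation genes en (2R:7411509-7415715) and gsb (2R:20949502-20952166), the T-box gene mid, the dorsal GATA factor pnr (3R:11851921-11867526), the adhesion molecules CadN, Ten-a and Toll-6, and ImpL2, a secreted insulin-binding protein. Their log2 ratios were 2.16 ± 0.14 for en, 2.09 ± 0.02 for gsb, 2.09 ± 0.51 for mid, 1.97 ± 0.32 for pnr, 1.80 ± 0.02 for ImpL2, 1.75 ± 0.23 for Toll-6, 1.67 ± 0.83 for Ten-a and 1.38 ± 0.14 for CadN (SD, n = 2). In the authors' deposited tables ImpL2 stood at FPKM 7.93 in control and 29.8 in depleted embryos for grhB37 and at 9.90 and 37.2 for grhIM. All but Toll-6 had a GRH peak at 2-3 h, 7 of 8 (87.5%) against 35.0% of 6314 other tested genes (odds ratio 13.0, Fisher's exact test, p = 0.00363). With loci extended by 10 kb the odds ratio was 5.18 (Fisher's exact test, p = 0.149), and over the alternatives it ran from 4.74 to 19.1.

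Genes grouped by their change with embryonic age differed in their ratios at 2-3 h, but these groups share the 2-3 h controls with the ratios. A gene low in those controls by chance looks both higher in depleted embryos and rising with age. The shares expected without a change were not computed. All 8 higher genes had at least 2-fold more RNA in the 11-12 h controls than in the 2-3 h controls. Of genes abundant in 2-3 h controls and low in 11-12 h controls, 64.7% of 235 were lower with grhB37 depletion (95% Wilson interval 58.4% to 70.5%) and 83.8% of 234 with grhIM (78.5% to 87.9%), and of genes rising with age 29.0% of 455 and 24.9% of 474 were lower.

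Early zygotic patterning genes fell as a group at 2-3 h, with a median log2 ratio of -0.34 over 31 genes (camera adjusted p = 1.53e-06, but adjusted p = 0.959 with an estimated correlation). The list calls at this stage are Cuffdiff's in both tables, and limma called 0 members of any list. Of 29 tested in both tables, en was the 1 called higher, 0 lower and 28 not called, and adjusted over the list alone 1 was higher and 0 lower. The hairy gene h had a log2 ratio of -0.64 ± 0.22, nullo, a cellularization gene, 1.02 ± 0.26 and wg 0.70 ± 0.30 (SD, n = 2). Ribosomal protein genes had a median of -0.24 over 91 genes (camera adjusted p = 4.97e-06, and adjusted p = 0.959 with an estimated correlation), but -0.04 without grhIM (camera adjusted p = 0.927), with RpL37b at 0.38 ± 0.33, RpS19b at 0.23 ± 0.48 and RpL21 at -0.32 ± 0.31 (SD, n = 2) and 0 of 78 called, and 0 adjusted over the list alone. Glial genes had a median of 0.06 over 11 genes (camera adjusted p = 0.0244, and adjusted p = 0.959 with an estimated correlation), led by nrv2, a sodium pump subunit of septate junctions, at 0.91 ± 0.08, with 0 of 5 called and 0 adjusted over the list alone. Without grhIM the early zygotic and glial lists did not pass either, but that fit leaves 1 ratio at 2-3 h and takes its spread from 11-12 h. In each allele alone the early zygotic median lay at percentile 0 of matched random lists (-0.267 for grhB37 and -0.415 for grhIM). The glial median, over 5 genes, lay at percentile 98.3 for grhB37 and 88.7 for grhIM. Epidermal and tracheal regulators had a median of 0.24 (camera adjusted p = 0.0768), led by bnl, the FGF ligand of tracheal branching, at 0.92 ± 0.01, with 0 of 14 called in both tables and 1 higher adjusted over the list alone. The other 20 lists had camera adjusted p between 0.155 and 0.956. Among them, en was the 1 called of 12 known GRH targets and ImpL2 the 1 called of 12 ecdysone pathway genes, both also when adjusted over the list alone. ImpL2 went against its list, whose median was -0.119 over 13 genes for grhB37 (percentile 1.14) and -0.439 over 12 for grhIM (percentile 0). The other 18 had 0 members called in both tables, with 1 higher in the salivary gland list adjusted over the list alone.

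The 2-3 h values rest on a weak match between the alleles. Across genes, which are not independent replicates, the log2 ratios of the 2 tables had r = 0.301, and limma called 0 genes higher and 0 lower at this stage, with 864 at unadjusted p under 0.05 and adjusted p from 0.325 to 0.623 for the 8 genes, while a fit of this stage alone called 30 higher and 18 lower.

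Depletion of zygotic grh at 11-12 h came with far more RNA of genes that mothers load into the egg. The authors' deposited tables called 287 genes higher and 30 lower in both replicates, from 1548 and 254 in replicate 1 and 328 and 33 in replicate 2. The largest finite mean folds among genes called in both replicates include swa (X:6257451-6259742), which localizes bicoid RNA, with a log2 ratio of 5.63 ± 0.65, pim (securin, 2L:10362989-10364092) with 5.12 ± 0.54, wisp, a cytoplasmic poly(A) polymerase, with 5.02 ± 1.86, and smg (3L:8983417-8991089), a repressor of maternal RNAs, with 5.00 ± 0.29 (SD, n = 2). The piRNA pathway genes tej and AGO3 had log2 ratios of 4.84 ± 0.70 and 4.72 ± 0.07, dob, a lipase, 4.18 ± 0.04, rpk, a sodium channel subunit, 4.08 ± 0.24, the mitotic kinase Nek2 3.75 ± 0.53 and CG8301 3.48 ± 0.56 (SD, n = 2). Other genes rose as far but fall outside that choice. Among them, named after their values were seen, are twe, a meiotic phosphatase called in neither replicate, at 6.38 ± 0.04 (SD, n = 2), and bcd, which has no finite fold in replicate 2. In the authors' deposited tables pim stood at an FPKM of 3.42 in control and 117 in depleted embryos of replicate 1 and at 5.47 and 293 in replicate 2. Of the 287 higher genes, 284 (99.0%) had an FPKM of at least 1 in a 2-3 h control, against 72.8% of 8806 genes not called (odds ratio 35.4, Fisher's exact test, p = 3.8e-34).

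Maternal transcripts rose as a list, with a median log2 ratio of 0.79 over 24 genes (camera adjusted p = 2.9e-09, and adjusted p = 0.562 with an estimated correlation). The median was 0.53 without replicate 1 and 1.10 without replicate 2 (camera adjusted p = 0.544 and 0.0954). In each replicate alone the median lay at percentile 100 of matched random lists. Of 21 tested, 6 were called higher, 0 lower and 15 not called, and 7 were higher adjusted over the list alone. Besides swa and smg they include CycB (cyclin B) at 4.62 ± 0.46 and the kinase polo at 3.78 ± 0.44 (SD, n = 2). Germline genes had a median of 0.59 over 12 genes (camera adjusted p = 0.000143, and adjusted p = 0.562 with an estimated correlation), with 2 of 11 called higher, AGO3 and the germ cell differentiation gene bam (3.24 ± 0.09), 9 not called, and 2 higher adjusted over the list alone. Without replicate 1 this median was 0.60 and without replicate 2 it was 1.17 (camera adjusted p = 0.715 and 0.225).

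Genes that fell at 11-12 h include enzymes of chitin and its precursors. The log2 ratio was -2.43 ± 0.42 for the chitinase Cht3 (2L:22892306-22918647), -1.71 ± 0.28 for knk (3R:5948087-5951386), whose product organizes chitin, and -1.98 ± 0.49 for Gfat1, which starts the synthesis of the chitin precursor (SD, n = 2). Larger falls were found for the serpin Spn42De (2R:2773057-2775767) at -4.35 ± 0.79, CG17843 at -3.36 ± 0.76, CG18519 at -3.11 ± 0.15, CG33978 at -3.08 ± 0.44, the merged locus CG34056,CG34057 at -2.58 ± 0.04 and CG1969 at -2.52 ± 0.22 (SD, n = 2). The glycosyltransferase gene tw had -2.37 ± 0.16, GNBP3, a sensor of fungal glucans, -2.21 ± 0.46 and CG8654 -2.0 ± 0.20 (SD, n = 2). The limma adjusted p of these 12 genes ran from 0.00499 to 0.0188. Of the 30 lower genes, 8 (26.7%) had an FPKM of at least 1 in a 2-3 h control (odds ratio 0.136, Fisher's exact test, p = 2.05e-07).

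Chitin synthesis and cuticle assembly genes fell as a list, with a median log2 ratio of -0.36 over 23 genes (camera adjusted p = 0.000734, and adjusted p = 0.562 with an estimated correlation). Without replicate 1 the median was -0.19 and without replicate 2 it was -0.49 (camera adjusted p = 0.867 and 0.87). Of 22 tested, 3 (Cht3, Gfat1 and knk) were called lower, 0 higher and 19 not called, and 4 were lower adjusted over the list alone. Neuronal genes had a median of -0.40 over 18 (camera adjusted p = 0.00866), epidermal and tracheal regulators -0.34 over 18 (0.0287), zona pellucida proteins -0.23 over 15 and known GRH targets -0.31 over 19 (both 0.0499), all with adjusted p = 0.562 with an estimated correlation. In the neuronal, epidermal and zona pellucida lists 0 of 16, 18 and 14 genes were called in both replicates by Cuffdiff and 0 adjusted over the list alone, while limma called 2, 1 and 3 lower. Their leading members were brp, an active zone protein, at -0.73 ± 0.33, SoxN, an epidermal regulator, at -0.62 ± 0.05, dys (dysfusion, of tracheal fusion) at -0.61 ± 0.10 and dp (dumpy, a giant matrix protein) at -0.66 ± 0.04 (SD, n = 2). Among 17 known targets 1, knk, was lower, also adjusted over the list alone, and krz (an arrestin) had a log2 ratio of 1.43 ± 0.44. In each replicate alone the medians of these lists lay low among matched random lists. In replicates 1 and 2 the percentiles were 0 and 0.1 for chitin, 0.31 and 0 for neuronal and 0.03 and 0.03 for epidermal genes. They were 0.18 and 0.01 for zona pellucida proteins and 0 and 0.08 for known GRH targets. Lists without a camera call lay low too, at 0 and 0.4 for septate junction and 0.04 and 0.46 for glial genes. The random lists were matched on mean expression and not on RNA in the 2-3 h controls. A low percentile may therefore partly reflect the rise of maternally loaded genes among the random lists. The camera calls held only with both replicates, and with 1 left out the spread came from the 2-3 h pair alone. Without replicate 1 the camera test called 1 list higher, none of those given above, and 0 lower at this stage, with known GRH targets at -0.06 (adjusted p = 0.867). Without replicate 2 it called 0 and 0.

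The other 17 lists had camera adjusted p between 0.0537 and 0.83 at 11-12 h. Adherens junction and polarity genes had a median of 0.28 (0.112) with 0 of 15 called by Cuffdiff in both replicates and 5 higher by limma, the apical kinase aPKC standing at 1.09 ± 0.12 and the FERM protein yrt at 1.23 ± 0.08 (limma adjusted p = 0.0109 and 0.0204). Septate junction genes had a median of -0.19 (0.112) with 0 of 26 called by Cuffdiff, 1 lower by limma, dlg1 at 0.57 ± 0.08 and cora at -0.52 ± 0.01 (SD, n = 2). In the heat shock and stress list Hsp23 (2.02 ± 0.15) and GstE1 (1.48 ± 0.11) were called higher, and in the housekeeping list RpII140, an RNA polymerase II subunit (1.88 ± 0.06). In the innate immunity list PGRP-LC, a peptidoglycan receptor, was lower (-1.55 ± 0.24). In the cuticle protein list the merged locus Lcp9,egg was higher (2.02 ± 0.25, SD, n = 2), and its values do not part Lcp9 from egg. By limma the calls were 3 higher and 1 lower in the heat shock list, 4 and 0 in the housekeeping list, 2 and 4 in the immunity list (higher for cact, 1.41 ± 0.50, and Tl, 1.20 ± 0.39, SD, n = 2) and 4 and 2 in the cuticle protein list. Adjusted over the list alone the calls were 2 higher in the heat shock list, 1 higher in the housekeeping list, 1 lower in the immunity list and 2 higher in the cuticle protein list, and 0 in the adherens and septate junction lists. The lists of early zygotic, neuroblast, glial, muscle, hemocyte, midgut, fat body, salivary gland, ecdysone, tanning and ribosomal genes had 0 members called in both replicates by Cuffdiff, and of these lists tanning had 1 higher adjusted over the list alone. In these lists limma called 1 early zygotic, 2 midgut and 2 tanning genes higher, and 1 neuroblast, 2 glial, 1 muscle, 1 fat body, 1 ecdysone and 2 tanning genes lower, leaving 0 hemocyte, salivary gland and ribosomal genes by either tool. Cuticle protein genes had a median of -0.28 over 35 genes in replicate 1 and 0.22 over 67 genes in replicate 2, so these values cover different members.

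At 11-12 h the lower genes were bound by GRH more often than other tested genes, and the higher genes less often before locus length was taken into account. Of 28 lower genes with a locus on the main arms, 23 (82.1%) had an 11-12 h peak against 48.6% of 9042 others (odds ratio 4.87, Fisher's exact test, p = 0.000421). Without replicate 2 it was 172 of 251 (odds ratio 2.4), and with loci extended by 10 kb the odds ratio was 9.88, the ends of the range over the alternatives. Among the lower genes named above with such a locus, all but CG18519 had one. Of 284 higher genes, 107 (37.7%) had a peak against 49.0% (odds ratio 0.629, Fisher's exact test, p = 0.000176), and within locus length classes this was 0.785 (p = 0.0576; 0 to 0.829 over the alternatives). Without genes at FPKM of at least 1 in a 2-3 h control, 3 higher and 22 lower genes remained in the count. Across genes the log2 ratios of the replicates had r = 0.812, and limma called 1440 genes higher and 369 lower. Without replicate 1 it called 125 and 81, and without replicate 2 it called 6 and 29. Without grhB37 and without grhIM the lower genes numbered 107 and 103.

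At 15-16 h, in 1 pair of libraries, midgut and immunity genes were higher and chitin and fat body genes lower. These 4 list calls did not hold with an estimated correlation (camera adjusted p = 0.194, 0.234, 0.713 and 0.713). This stage has no spread of its own, so its limma and camera p-values borrow that of the other stages and do not measure how replicates would vary. The log2 ratios are on the log2(FPKM + 1) scale. Among genes with a name of their own, 1204 were called higher and 1542 lower in the authors' deposited table, by a test that compares these 2 libraries and not the conditions. The log2 ratio was 5.04 for Lip3 (a lipase, 3R:9195370-9197626), 4.77 for AttB (an antibacterial attacin, 2R:10636728-10637670), 4.74 for Prx2540-2 (a peroxiredoxin), 4.53 for Jon66Ci (a digestive protease, 3L:8384640-8385477) and 4.51 for CG34203. Further rises were CG34221 at 2.92, Jhe (juvenile hormone esterase) at 2.52, Cpr49Ad (a cuticle protein) at 2.46, CG3292 at 2.16 and CG18557 at 2.11. The falls were led by CG17325 (2L:18813009-18813941) at -9.11, CG40198 at -7.19, Obp83g (an odorant-binding protein) at -6.84, Cyp6d2 (a cytochrome P450) at -6.24, CG17843 at -6.05, CG13059 at -5.95, CG15515 at -5.80, CG12766 at -5.74 and CG31321 at -4.21. In the authors' deposited table CG12766 stood at an FPKM of 225 in the control and 3.22 in the depleted embryos. The limma adjusted p of these 19 genes, which assumes that this lone ratio varies like the others, ran from 0.00244 to 0.0188. The receptor gene tor had a log2 ratio of -3.81 with limma adjusted p = 0.0674, and limma called 726 genes higher and 899 lower. The shared spread is narrow for genes with a log2 ratio of 0 ± 0 (SD, n = 2) at 2-3 h, such as CG12766, CG18557 and Cpr49Ad. Their small p-values thus say little about the spread at 15-16 h. The limma counts lean on the 2-3 h tables through the shared spread. Without grhB37 they were 213 and 286, and without grhIM 210 and 275.

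In the 1 pair of libraries at 15-16 h midgut genes had a median log2 ratio of 1.70 over 19 genes, at percentile 100 of matched random lists (camera adjusted p = 7.22e-23 with the borrowed spread, and adjusted p = 0.194 with an estimated correlation). Of 19 members 10 were called higher, 1 lower and 8 not called in the authors' deposited table, and the same numbers held adjusted over the list alone. Besides Jon66Ci they include deltaTry (a trypsin) at 3.02, Amy-p (amylase) at 2.94 and Jon65Aii at 2.66. At 2-3 h deltaTry, Amy-p and Jon65Aii had a log2 ratio of 0 ± 0 (SD, n = 2). The spread borrowed for such genes is narrow and says little about 15-16 h. Innate immunity genes had a median of 0.95 over 19, at percentile 100 (camera adjusted p = 1.04e-09, and adjusted p = 0.234 with an estimated correlation). Of these, 8 were called higher, 1 lower and 10 not called, 8 and 1 adjusted over the list alone, with AttA at 3.46, Dro (drosocin) at 2.79 and PGRP-SB1 at 2.07.

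Chitin synthesis and cuticle assembly genes were lower in this pair of libraries, with a median of -0.67 over 23 genes (camera adjusted p = 0.0213 with the borrowed spread, and adjusted p = 0.713 with an estimated correlation), at percentile 0 of matched random lists. Of 23 members 12 were called lower, 2 higher and 9 not called in the authors' deposited table, and 14 lower and 2 higher adjusted over the list alone. The chitin-binding obst-B (2L:10032694-10038954) had a log2 ratio of -3.52, Gfat1 -2.81, Cht3 -2.65 and the chitin deacetylase Cda4 -2.62. Fat body genes were lower, with a median of -0.63 over 6 (camera adjusted p = 0.0262, and adjusted p = 0.713 with an estimated correlation), at percentile 1.65, with 1 of 7 called higher and 3 lower, also adjusted over the list alone. Without replicate 1 at 11-12 h, whose spread is shared, both lists had camera adjusted p = 0.996, and without replicate 2 it was 0.992. Lsp1gamma, a larval storage protein, stood at -3.43, the lipoprotein Rfabg at -1.04 and Adh at 0.83.

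The other 20 lists had camera adjusted p between 0.0706 and 0.977 at 15-16 h. Of the authors' calls in the deposited table, given with the percentile of the median among random lists, muscle genes had 0 higher and 9 lower of 20 (percentile 0.02; bt -2.10 and sls -1.44, both giant titin-like proteins, and Mhc, myosin heavy chain, -1.12). Heat shock and stress genes had 5 higher and 10 lower of 21 (0.02; W, the cell death gene hid, -1.65, and GstD2 2.29). Epidermal and tracheal regulators had 1 higher and 4 lower of 18 (6.5; dys -3.87, 3R:21902314-21924433, and bnl -1.63), and known GRH targets 1 and 6 of 18 (3.91; Ddc -1.29, knk -1.04, verm -0.72 and Idgf4 0.72). Neuronal genes had 0 and 5 of 18 (2.04; para, a sodium channel, -1.09), hemocyte genes 0 and 4 of 14 (1.72; He -1.38), salivary gland genes 0 and 3 of 11 (4.39; PH4alphaSG2 -1.61) and ecdysone pathway genes 2 and 2 of 17 (2.32; Cyp18a1 1.39). Cuticle proteins went both ways, 19 higher and 23 lower of 82 (2.6; Cpr57A -4.83 and TwdlB 3.66), as did tanning genes, 2 and 2 of 12 (12; Dat 2.37 and laccase2 -1.64). Ribosomal protein genes had 12 higher and 0 lower of 91 (88.3; RpS20 1.47) and housekeeping genes 3 and 0 of 12 (57.2; betaTub56D 0.93).

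Septate junction genes had 3 higher and 4 lower of 26 (percentile 26.4; Ssk -0.98), adherens junction genes 0 and 2 of 15 (14.1; p120ctn -0.63), zona pellucida proteins 3 and 3 of 11 (83; neo 0.81 and mey -1.04), early zygotic genes 2 and 3 of 24 (64), maternal transcripts 0 and 3 of 17 (23.9; Hsp83 -1.10), neuroblast genes 2 and 0 of 13 (62.3), glial genes 1 and 2 of 10 (62) and germline genes 1 and 0 of 11 (13.1; tud 1.02), by the authors' deposited table. Adjusted over the list alone the higher and lower calls were 0 and 11 for muscle, 21 and 26 for cuticle proteins, 4 and 4 for septate junction, 4 and 3 for zona pellucida, 11 and 0 for ribosomal and 3 and 1 for housekeeping genes, and as given for the rest.

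**Figure D3:**
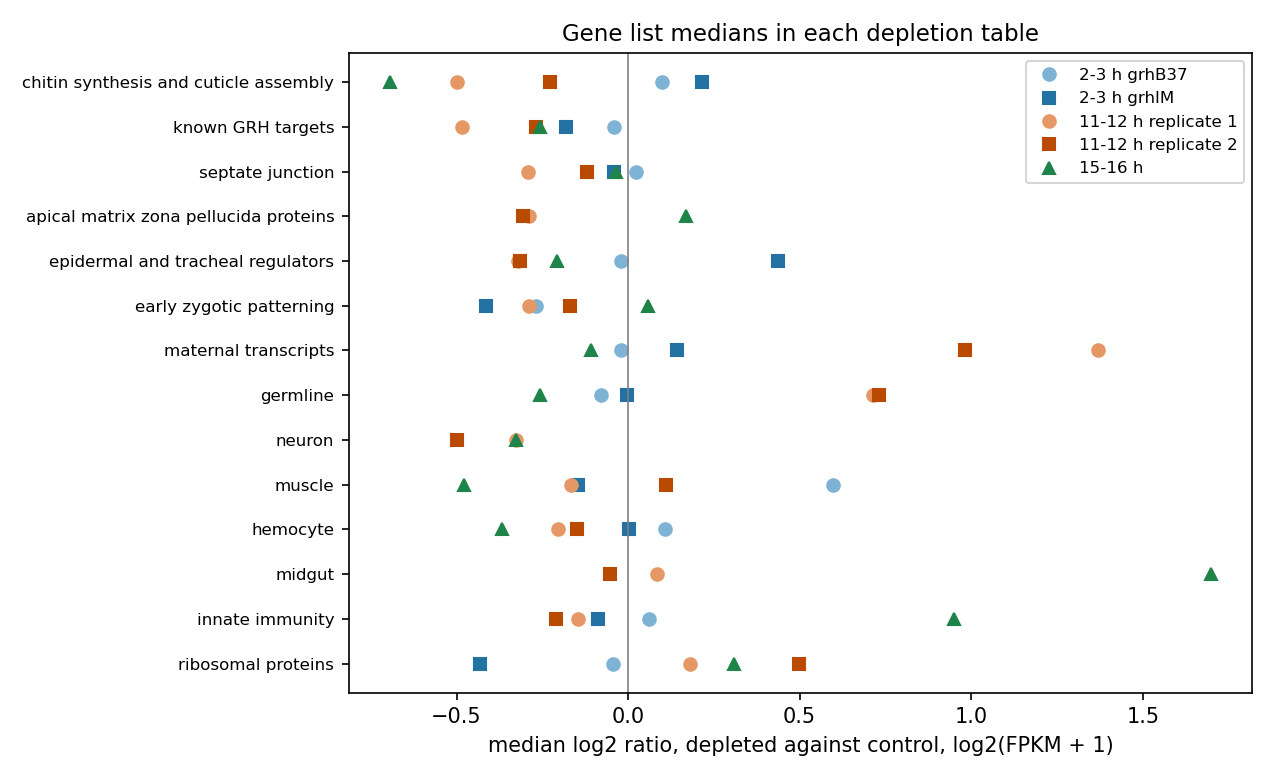
Points give the median log2 ratio of depleted against control embryos on the log2(FPKM + 1) scale for 14 gene lists, 1 symbol per table (circles and squares for the pairs at 2-3 h and 11-12 h, triangles for 15-16 h). Maternal transcripts reach 1.37 and 0.98 in the 11-12 h tables, midgut genes 1.70 and chitin genes -0.69 at 15-16 h.

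Binding did not part the 15-16 h lower genes from the rest. Of the lower genes the share with a 15-16 h peak was 60.3% against 59.9% of other tested genes (odds ratio 1.02, Fisher's exact test, p = 0.799), running from 0.903 to 1.15 over the alternatives, with p = 0.0252 for peaks found by both antibodies and p = 0.043 without an extension. Higher genes had a peak in 51.5% against 61.0% (odds ratio 0.679, Fisher's exact test, p = 4.15e-10), and within locus length classes the odds ratio was 0.957 (p = 0.498).

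The same genes fell at 11-12 h and 15-16 h more often than chance gives, which was not so for rises. Of 8778 genes tested at both stages, 20 were lower at both against 4.25 by chance (odds ratio 13.1, Fisher's exact test, p = 4.9e-11; 5.11, with 106 against 34.3, without replicate 2 at 11-12 h), among them Cht3, knk, Gfat1, tw, Spn42De, CG17843, CG33978, CG1969 and CG8654. Higher genes shared 17 against 28.1 by chance (odds ratio 0.57, Fisher's exact test, p = 0.0254; 0.669 with p = 0.0736 without replicate 1 at 11-12 h). GNBP3, Nep2 and CG13324 were lower at 11-12 h and higher at 15-16 h, the last pair named after their values were seen. No gene was shared between the 8 genes higher at 2-3 h and the genes higher later, where chance gives 0.327 at 11-12 h and 0.62 at 15-16 h (Fisher's exact test, p = 1 for both). The limma contrast of 15-16 h against 11-12 h called 723 genes with a larger and 1329 with a smaller log2 ratio at the later stage, against 193 and 570 without grhB37 and 186 and 520 without grhIM.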

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

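The limma contrast, the list tests, the odds ratios of a GRH peak and the comparison of the 15-16 h calls with the change between controls were set before their results were seen, while the tests of early RNA shares, of the listed groups between controls, of chromosome arms, of age at 2-3 h and of genes that rise with age, and the limits set on the odds ratios, were chosen after.

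The depletion effect differed between 15-16 h and 11-12 h for 723 genes with a larger and 1329 with a smaller log2 ratio at the later stage, by limma's contrast of the stage means. The counts fell to 193 and 570 without grhB37 and to 186 and 520 without grhIM. Of the largest rises and falls named above, only those with limma adjusted p under 0.05 for this contrast are given. That choice sets the range of adjusted p. Not passing were wisp, Spn42De, CG33978, Cht3, CG8654, CG1969 and tor. Genes among the largest rises at 11-12 h had smaller ratios at 15-16 h. The differences were -5.48 for swa, -4.75 for tej, -3.98 for dob, -3.16 for CG8301 and -3.72 for Nek2. They were -5.05 for pim, -5.04 for AGO3, -5.00 for smg and -4.05 for rpk. Some of the genes that fell at 11-12 h had differences, 2.94 for CG18519, -2.68 for CG17843, 3.23 for GNBP3, 1.13 for CG34056,CG34057 and 0.97 for tw. Genes that rose at 15-16 h had differences of 4.56 for CG34203, 2.15 for CG18557, 4.76 for Lip3, 4.73 for AttB, 3.62 for Prx2540-2, 1.92 for CG34221, 4.52 for Jon66Ci, 2.30 for Jhe, 2.39 for Cpr49Ad and 2.09 for CG3292. Genes that fell at 15-16 h had differences of -8.61 for CG17325, -6.71 for CG40198, -4.61 for Obp83g, -2.90 for CG31321, -6.32 for Cyp6d2, -4.64 for CG13059, -6.11 for CG15515 and -5.73 for CG12766. The limma adjusted p of these genes ran from 0.0049 to 0.0446, with the single 15-16 h ratio assumed to vary like the others.

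The first pattern weighed is the rise of maternally loaded genes at 11-12 h. Whole embryos of 2-3 h in the depleted pools are argued against, since early zygotic genes implied a median share of -0.0102% of 2-3 h RNA in replicate 2 and -0.113% in replicate 1. Lost repression at bound loci is argued against as the whole cause by an odds ratio of 0.629 for a GRH peak (95% interval 0.488 to 0.808), or 0.785 within locus length classes (0.61 to 1.01, which includes 1), both under a limit of 1.5 that was set after these values were seen, and stays open for part of the genes. Undegraded maternal RNA stays open: genes abundant in 2-3 h controls and low in 11-12 h controls implied a median share of early RNA of 11.5% in replicate 2 (quartiles 0.485% to 26.7%) and 15.4% in replicate 1 (0.026% to 39.0%), and a candidate explanation is unfertilized or arrested eggs, or slower clearance, among the depleted embryos. Which of these applies was not tested, and an effect of grh on the clearance of maternal RNA, the biological explanation, was not tested apart from them.

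The next pattern is the opposed gene groups at 15-16 h, with midgut and immunity genes higher and chitin and fat body genes lower, list calls of 1 ratio with a borrowed spread that did not hold with an estimated correlation (camera adjusted p from 0.194 to 0.713) and, for chitin and fat body, with a pseudocount of 5 (0.284 and 0.277). Age was weighed by the change from the 11-12 h to the 15-16 h controls, and the 15-16 h control also enters the calls. A low control favours both a higher call and a fall, and a high one both a lower call and a rise. A younger age is argued against as the whole cause of the called genes. Of the higher genes 63.6% had risen, against 47.0% of genes not called. An older age is not decided, since 67.8% of the lower genes had risen, as the shared control favours. For the listed groups an older age stays open. Of 38 midgut and immunity genes 86.8% had risen (95% interval 72.7% to 94.2%). Of 30 chitin and fat body genes it was 36.7% (21.9% to 54.5%). Muscle genes, of which 85.0% had risen, went against it with 0 higher and 9 lower of 20 in the authors' deposited table. Ribosomal protein genes, of which 89.0% had risen, went with it at 12 higher and 0 lower. Cuticle proteins, of which 82.9% had risen, went both ways at 19 higher and 23 lower. Lost activation at bound loci is argued against as the whole cause of the lower genes by an odds ratio of 1.02 (95% interval 0.908 to 1.14), or 0.997 within locus length classes (0.888 to 1.12). Differences between the mutant second chromosome and the balancer it was kept over could account for part. Genes changed at least 4-fold lay on 2L and 2R in 47.9% against 38.1% of cases (odds ratio 1.49, p = 1.55e-05, Fisher's exact test, and 1.66 counted once per 50 kb window). The 11-12 h embryos carry the same chromosomes, so such differences should show there too, but the odds ratio was 0.96 (0.684 to 1.34). The window count and the 11-12 h condition were added after the first value was seen. The balancer explanation cannot be told apart from effects of grh, which lies on the same chromosome. With 1 library per group an effect of grh loss remains an untested alternative.

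The last pattern is the rise of regulatory genes at 2-3 h with a lower median of early zygotic genes. Of those genes 0 of 29 were called lower. Their list did not pass with an estimated correlation (camera adjusted p = 0.959) or without grhIM, which leaves 1 ratio. In each allele alone their median lay at percentile 0 of matched random lists. An age ahead of the controls may account for the pattern, but the values cannot decide. Of genes falling with age, 64.7% were lower with grhB37 depletion and 83.8% with grhIM. Those genes were picked for high values in the same 2-3 h controls, which favours lower ratios without any change. The share expected without a change was not computed. Lost repression at bound loci may also account for the higher genes, with an odds ratio of 13.0 for a 2-3 h peak and of 8.53 (p = 0.0265, Fisher's exact test) against 1622 other genes that rise with age. Both stay open.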

How the results depend on the processing

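Of 360 alternatives over 58 results, those without genes at FPKM of at least 1 in a 2-3 h control and those with a score of at least 60 were chosen after seeing the data, and the others were planned. For counts, shares and odds ratios that answer a comparison, 205 alternatives kept the direction and side of the threshold or stayed within 1.5 times, 58 moved a value further, 5 turned a direction, 3 gained and 5 lost a call. For the medians of named lists, 41 kept the call and 43 lost it. No paired analysis was possible because the replicate labels are shared between stages and depletions that are never compared sample to sample, and each depleted library already stands against its own control. The planned GRH motif test was not run. Read depth is unknown, so what depth limits could not be estimated. The cause was not tested for any value below, unless the alternative itself uses fewer genes or samples.

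Without 1 allele the authors' calls at 2-3 h were 9 to 39 higher and 2 to 9 lower, and without 1 replicate at 11-12 h 328 to 1548 higher and 33 to 254 lower. At q under 0.01 there were 0 higher at 2-3 h and 161 higher and 14 lower at 11-12 h. A change of at least 2-fold left 597 higher and 822 lower at 15-16 h. Without genes at FPKM of at least 1 in a 2-3 h control there were 3 higher at 11-12 h and 582 higher and 643 lower at 15-16 h, from fewer genes.

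The odds ratio of rising at 11-12 h and 15-16 h was 0.669 to 0.67 without 1 replicate at 11-12 h (Fisher's exact test, p = 0.0736 without replicate 1), that of rising then falling 1.06 to 1.21, and that of rising at 2-3 h and 11-12 h 0 to 2.71. Without grhB37 that of rising at 2-3 h and 15-16 h was 0 (Fisher's exact test, p = 0.0454, range over the alternatives 0.0454 to 1). The odds ratio of a GRH peak was 5.18 with 10 kb for higher genes at 2-3 h (alternatives 4.74 to 19.1), 0.785 within length classes and 0 without genes at FPKM of at least 1 in a 2-3 h control for higher genes at 11-12 h (0 to 0.829), and 0.957 within length classes for higher genes at 15-16 h (0.615 to 0.957). For lower genes at 15-16 h it was 1.12 with 0 kb, 0.903 with 10 kb, 1.15 with peaks of both antibodies and 0.997 within length classes.

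With an estimated correlation the camera test called 0 lists higher and 0 lower at 2-3 h, 11-12 h and 15-16 h. That version also has fewer degrees of freedom. A pseudocount of 5 left 0 higher at 2-3 h and 0 lower at 15-16 h. With each replicate left out the lists called were 0 to 1 higher and 0 to 2 lower at 2-3 h, 0 to 2 higher and 0 to 4 lower at 11-12 h, and 0 to 4 lower at 15-16 h.

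For limma, a pseudocount of 0.1 gave 191 lower at 11-12 h, 183 higher and 298 lower at 15-16 h, and 205 larger and 822 smaller for the difference between these stages. A pseudocount of 5 gave 682 lower at 11-12 h, 1160 higher at 15-16 h and 1236 larger for the difference, and no filter gave 788 higher at 11-12 h. The 2-3 h stage fitted alone gave 30 higher and 18 lower. With each replicate left out limma called 6 to 989 higher and 29 to 107 lower at 11-12 h, 210 to 684 higher and 275 to 763 lower at 15-16 h, and 186 to 624 larger and 520 to 708 smaller for the difference.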

Other observations

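The tests in this part were all chosen after the data were seen. Wing disc peaks, counted over all members of a list, lay at 13 of 18 epidermal and tracheal regulators, 11 of 22 chitin and cuticle assembly genes, 9 of 15 adherens junction genes, 10 of 26 septate junction genes, 10 of 16 neuroblast genes, 7 of 11 glial genes, 12 of 22 ecdysone pathway genes, 10 of 23 heat shock and stress genes, 2 of 18 neuronal genes, 2 of 19 midgut genes and 8 of 117 cuticle proteins. The lists were not tested against each other. Neuroblast genes were bound at all 4 embryo stages in 9 of 16 cases (odds ratio 3.41, Fisher's exact test, adjusted p = 0.048), and within locus length classes the adjusted p was 0.46. Housekeeping genes were bound in 7 of 12 cases (3.71, adjusted p = 0.052, and adjusted p = 0.03 within length classes). Neuronal genes were bound at all 4 stages in 4 of 18 cases, with an odds ratio of 0.248 within length classes (adjusted p = 0.034). Ribosomal protein genes were bound in 15 of 91 cases (0.521, adjusted p = 0.048), and within length classes the odds ratio was 1.06 (adjusted p = 0.89).

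The 17 genes called higher at both 11-12 h and 15-16 h include the glutathione transferases GstE1 and GstZ1, the lysosomal protease gene cathD, the proteasome subunit gene Prosbeta7, O-fut1, which modifies Notch, and the mitotic kinase gene gwl, named after their values were seen. Across 13560 genes, which are not independent replicates, the 11-12 h depleted libraries correlated with the 2-3 h controls at r from 0.751 to 0.799 and the 11-12 h control libraries correlated with the same 2-3 h controls at 0.696 to 0.727. At 15-16 h the correlations with the 2-3 h controls were 0.528 and 0.534 for the depleted library and 0.526 and 0.53 for its control.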
